A study of Homo sapiens with 4 samples.

How the data were processed

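Single-cell RNA sequencing was carried out on follicular aspirates from 4 donors undergoing in vitro fertilisation, 1 library per donor. Per the labels' protocols, the cells left in the aspirate after the cumulus-oocyte complexes had been taken out were treated to lyse red blood cells and passed through a strainer, samples below a viability limit were not processed, and libraries were made with the 10x Chromium 3' v3 kit. The labels place the 4 libraries in 1 group, as separate donors, so libraries were the replicates and every comparison was between cell classes within them. No batch or date was used, since the labels used here give none.

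The deposited values of each library are raw counts of unique molecular identifiers (UMIs) per gene and barcode, made by the authors with Cell Ranger 6.0.2, per the file headers. Per the submitters' processing notes the genome build was GRCh38. The annotation release is not given in the sources used here, and genes are named by the symbols the files pair with their identifiers. Each library held 36601 genes. The values were whole numbers and were used without normalization by the authors. Only barcodes that the authors had called as cells were in the files.

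Cells were kept with at least 300 genes, at least 500 UMIs and at most 20% of UMIs on the 13 mitochondrial genes. Doublet scores were computed with a deterministic implementation of the Scrublet method, because repeated runs of the packaged version differed, and the highest-scoring cells of each library were removed, in number 0.8% of the library per 1000 barcodes. The method's automatic threshold marked 10 of 7012 cells (0.143%), too few to have worked, and served only as an alternative. XIST, TSIX and Y-linked genes were dropped before any sum.

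Counts were scaled to 10000 per cell and log-transformed in scanpy 1.11.5. From 2000 highly variable genes, chosen with the library as batch key, 30 principal components were taken, and an exact graph of 20 nearest neighbours, weighted by shared neighbours, was divided by Leiden clustering (leidenalg 0.10.2) at resolution 1.0. The 398 genes of the 20 tested lists were kept out of the clustering genes, as were mitochondrial and ribosomal protein genes. Leukocyte-like cells were re-clustered at resolution 1.0 and granulosa-like cells at 0.5. No batch integration was used.

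Clusters were named "-like" from 164 marker genes. A cluster went to the class with most markers among its 10 leading genes by fold, with ties settled by the number of markers more than 1 log2 unit above the other cells. This order of the steps was chosen after the clusters were seen. A cluster resting on fewer than 3 markers, or with a median UMI count under 1/3 of its library's and no marker among its 10 leading genes, stayed unnamed. Leading genes were ranked by fold with a pseudocount of 10 CPM (counts scaled to 1e6 per sum) among genes detected in a share of at least 0.1 of the cluster's cells. Shares of cells are from the first clustering, except those of CD4 and CD8 T-like cells, which are from the re-clustering, and tests used the classes of the re-clustered leukocytes, where T-like cells numbered 1858 rather than 1869 and monocyte or macrophage-like cells 1317 rather than 1386. In the re-clustering a group of 115 cells was named mast or basophil-like, and the 19 cells first named plasmacytoid dendritic-like were named plasma-like. Granulosa-like sub-clusters are given by number.

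Raw counts were summed per library and class where a class had at least 10 cells, and classes with sums in at least 3 libraries were tested. Genes passing filterByExpr were tested with edgeR 4.0.16 (R 4.3.3), using TMM scaling, glmQLFit and glmQLFTest with the library as block, and adjusted by the Benjamini-Hochberg method at 5% FDR. The standard error of a log2 fold change was taken from the fold change and the F statistic. Both sums of a pair came from the same donor. Deviations from the class means correlated at 0.158 to 0.394 between the paired sums of a library in the leukocyte against granulosa comparison, above the highest correlation with another library in each of the 4. Where edgeR estimated no variation of the spread between genes (B-like and neutrophil-like cells, granulosa-like sub-clusters 2 and 3), p-values of single genes are too small to be read and are not given, and the counts of genes given there rest on them. The standard errors given there come from the same F statistic and are too small as well. The p-values of lists there come from camera's own fit. Because classes were made from the same counts, p-values are also too small for genes that formed the clusters.

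The 20 gene lists cover steroid hormone synthesis, cholesterol synthesis and uptake, the ovulatory response to luteinising hormone (LH), prostaglandins and leukotrienes, chemokines, cytokines, growth factors, cytokine and chemokine receptors, growth factor receptors, extracellular proteases and inhibitors, extracellular matrix, MHC class II presentation, cytotoxic granules, complement, classically activated and alternatively activated or resident macrophages, hypoxia and glycolysis, interferon response, dissociation stress and cell cycle. Lists were tested with camera in limma 3.58.1, with a preset correlation of 0.01 and then with an estimated correlation, and with fry, adjusted over the lists of a comparison. The fry p asks only whether a list's genes move on balance in 1 direction. The genes named are, per list, the 2 members with the largest absolute fold change among those past 5% FDR that differ in the same direction in every library, or, for single leukocyte classes and granulosa-like sub-clusters, the 3 such members per direction over all lists. A further 24 genes of ovulation and inflammation were fixed by name. Some genes that this rule names are not reported here. The samples' design, cell filters, markers, lists, tests, this naming rule and the other settings, apart from those stated to be later, were set before the data were examined.

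For a gene with 0 counts in a class the fold is a lower bound against a floor of 3 counts over the class. With 1 to 3 counts the ratio of summed CPM is given with its exact 95% counting interval. Shares of single libraries carry exact Clopper-Pearson 95% intervals. These intervals and floors cover counting error only. The leukocyte and granulosa shares were compared by an exact two-sided sign-flip test over the 4 libraries. A ligand was assigned to a class where that class had the highest CPM in every library with a sum of it. Free RNA was measured from the marker genes of 1 class in cells of another.

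The fit was run on simulated data with 200 genes changed by 2-fold or 4-fold. For leukocyte against granulosa it recovered 59% and 86%, with 9 false calls among 154. For monocyte or macrophage against T and NK it recovered 77% and 93% (19 among 189). For NK against T it recovered 74% and 97% (10 among 181). False calls exceeded 5% of calls each time. The first comparison called 9737 of 14351 genes, and the fit was not tested under such broad change.

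Other settings, chosen beforehand, were DESeq2's size factors in edgeR, DESeq2 1.42.0 itself, no filter on low counts, no block, each library left out, a mitochondrial limit of 10%, no cell filter, no doublet removal, the automatic doublet threshold, first clusterings at resolution 0.5 and 2.0, clustering of each library on its own, clustering with the tested lists, and cells thinned to 2000 UMIs. Other versions of the granulosa-like class, with cluster 1 added or divided at 2% mitochondrial UMIs, were chosen after seeing the data, and so was the use of the cell and clustering settings for the difference between the leukocyte-like and granulosa-like shares. Other tools were Python 3.11.15, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9 and matplotlib 3.10.9. Gene coordinates were not used here.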

Results

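Follicular aspirates are the fluid and cells drawn from ovulatory follicles at oocyte retrieval. Cells of such aspirates were profiled by droplet-based single-cell RNA sequencing in 4 donors, with 1 library each, in 1 group. The protocol describes cells that remained after removal of the cumulus-oocyte complexes, whereas the cell type in the labels names those complexes. Whether the granulosa-like cells include cumulus cells is therefore not known. Red blood cells were lysed in processing, and no blood sample was among the 4 libraries. Leukocytes of the follicle can therefore not be told apart here from those of blood drawn with the fluid. The study asked which leukocytes are present in the ovulatory follicle and what they contribute to ovulation. The comparisons are therefore between cell classes within the same libraries, and levels given with ± are means over the donors' libraries. Medians and CPM of single clusters, levels of non-mitochondrial UMIs and ratios with a counting interval are over the cells of all libraries as a pool.

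The 4 libraries held 2067, 3456, 2452 and 1173 barcodes with 22396173, 31805752, 37937845 and 11439539 UMIs in replicates 1 to 4. Of the 9148 barcodes, 1735 (18.97%) exceeded 20% mitochondrial UMIs, with 9.14% in replicate 1 and 24.5% in replicate 2 as the extremes. A further 401 barcodes within that limit had fewer than 300 genes, and a median of 94.7% of their UMIs came from haemoglobin genes. After removal of 189 presumed doublets, 1808, 2249, 1863 and 903 cells were kept, 6823 in all. Median UMIs per kept cell were 6070, 4702, 6770 and 6421, and median genes were 1891, 1665, 2082 and 2131.

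Leukocyte-like cells made up most of the kept cells in 3 of the 4 aspirates, and most of all deposited barcodes, without a cell filter, in 2 of 4 (81.4%, 38.4%, 50.2% and 49.8% in replicates 1 to 4). Their share was 62.4% ± 17.3 (SD, n = 4), and T-like cells (26.6% ± 16.8) and monocyte or macrophage-like cells (21.5% ± 6.92) were their main parts. Granulosa-like cells, the steroid-producing cells that line the follicle, made up 20.04% ± 14.4. Smaller classes were NK-like cells (5.60% ± 3.17), dendritic-like cells (4.77% ± 0.595), B-like cells (1.66% ± 1.22), neutrophil-like cells (1.53% ± 1.44), platelet-like cells (0.868% ± 0.730), mast or basophil-like cells (0.349% ± 0.337), theca or stroma-like cells (0.344% ± 0.195) and plasmacytoid dendritic-like cells (0.323% ± 0.208). Cluster 1, with 957 cells and a share of 16.4% ± 12.7, stayed unnamed.

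The spread between donors was wide for every large class. Leukocyte-like cells were 87.4% of the cells in replicate 1 (exact 95% interval 85.8 to 88.9), 47.6% in replicate 2 (45.5 to 49.7), 58.3% in replicate 3 (56.1 to 60.6) and 56.1% in replicate 4 (52.8 to 59.4). Granulosa-like cells were 7.91%, 34.9%, 29.8% and 7.53% in the same order. No neutrophil-like cell was found among the 1863 kept cells of replicate 3, which allows a share of up to 0.198% of kept cells. The neutrophil-like cluster had a median of 657 UMIs, near the minimum UMI count for a kept cell. Barcodes below that minimum, or not called as cells by the authors, were not counted. The neutrophil-like shares are therefore of kept cells only, and the share in the aspirate was not determined. The mast or basophil-like share depended on the clustering, since re-clustering the leukocyte-like cells gave 115 such cells, 75 of them in replicate 3, where the first clustering gave 0. Of the 115, 81 were in the monocyte or macrophage-like cluster 17 of the first clustering (83 cells, median 879 UMIs) and 19 in its mast or basophil-like cluster. Other classes moved too. With each library clustered on its own, replicate 4 had 127 monocyte or macrophage-like cells, against 254 in the re-clustering. Among kept cells the leukocyte-like share exceeded the granulosa-like share in 4 of 4 libraries, by 42.3 ± 28.8 percentage points (SD), with an exact two-sided sign-flip p of 0.125, the smallest that 4 libraries allow. In settings tried for this difference after seeing the data, replicate 2 had the larger granulosa-like share without a cell filter (1351 against 1326 cells), at a clustering resolution of 0.5 (1169 against 1080) and with cluster 1 counted as granulosa (1159 against 1071). The difference was then 25.4 ± 30.5, 26.5 ± 34.1 and 26.0 ± 34.2 points, in 3 of 4 libraries, with an exact p of 0.25 each. Counted over all leukocyte-like cells, T-like cells were 40.2% ± 13.1, monocyte or macrophage-like cells 36.5% ± 14.5, NK-like cells 8.81% ± 3.58 and dendritic-like cells 8.004% ± 2.004. In the re-clustering of leukocyte-like cells, CD4 T-like cells were 19.7% ± 5.50 of them and CD8 T-like cells 15.9% ± 11.7, with 206 T-like cells in neither.

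**Figure D1:**
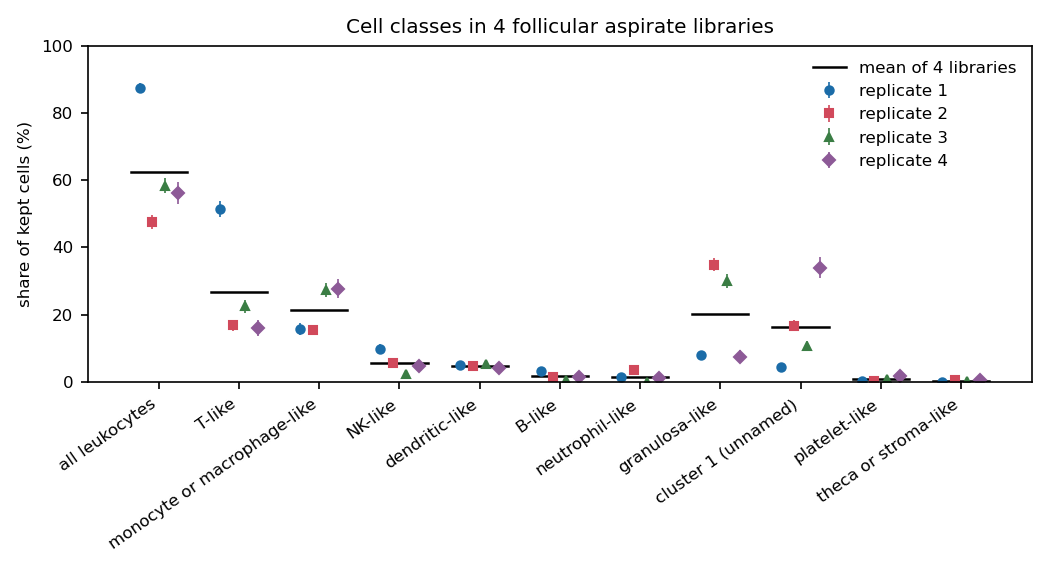
Share of kept cells (percent, vertical axis) in each cell class, with a point and its exact 95% interval for each of the 4 libraries and a black line at the mean. Leukocyte-like shares ran from 47.6% to 87.4%, granulosa-like shares from 7.53% to 34.9% and the unnamed cluster 1 from 4.31% to 33.9%.

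Granulosa-like barcodes came in 2 kinds that differed in RNA content. Clusters 4 (549 cells) and 12 (201 cells) had median mitochondrial shares of 13.5% and 12.9%, and MALAT1, a long non-coding RNA held in the nucleus, took a median of 6.62% and 4.73% of their other UMIs. Clusters 6 (546 cells) and 11 (255 cells) had 0.920% and 0.754% mitochondrial UMIs and 0.0353% and 0.0560% MALAT1. The unnamed cluster 1 resembled the latter pair, with 0.552% mitochondrial UMIs, 0.0415% MALAT1 and a median of 1532 UMIs, and its leading genes included STAR, FDX1 and DHRS9. STAR, which carries cholesterol into mitochondria for steroid synthesis, reached 3495 CPM of non-mitochondrial UMIs in cluster 1 and PTPRC, the pan-leukocyte CD45 gene, 9.63 CPM.

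**Figure D2:**
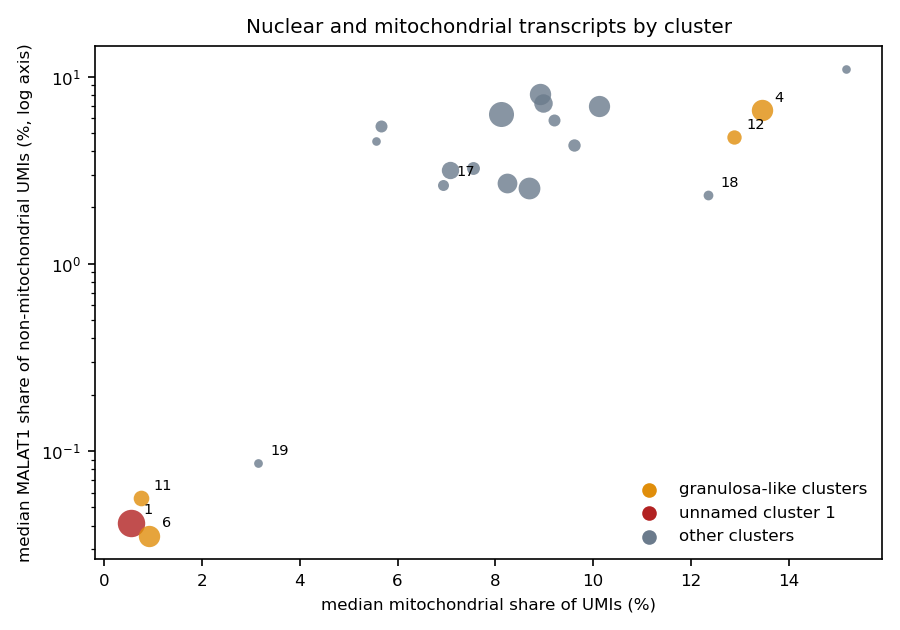
Median mitochondrial share of UMIs (percent, horizontal axis) against the median MALAT1 share of non-mitochondrial UMIs (percent, log axis) for each of the 21 clusters, with dot area by number of cells. Clusters 1, 6 and 11 lie at 0.0415%, 0.0353% and 0.0560% MALAT1, whereas granulosa-like clusters 4 and 12 lie at 6.62% and 4.73% MALAT1.

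The first comparison asked which genes separate leukocyte-like from granulosa-like cells of the aspirates. Sums weigh cells by their UMIs, and granulosa-like sub-cluster 1, described below, had 568 of the 1551 granulosa-like cells but most of their UMIs. It gave 7553120 of 7785975, 7927946 of 12323539, 12806994 of 16877273 and 1500742 of 1676274 in replicates 1 to 4. Granulosa-like levels and folds are therefore mainly those of sub-cluster 1. Most measured chemokine, cytokine, antigen presentation and cytotoxic genes were higher in leukocyte-like cells, and most genes of steroid and cholesterol synthesis, extracellular matrix and growth factors were higher in granulosa-like cells. As lists, 15 of 20 passed with camera's preset correlation and 0 with an estimated correlation (lowest adjusted p = 0.222). STAR stood at 1747 ± 859 CPM in granulosa-like cells and 12.4 ± 5.49 CPM in leukocyte-like cells (SD, n = 4). HLA-DRA, an MHC class II chain, stood at 4612 ± 618 CPM in leukocyte-like cells and 21.3 ± 13.6 CPM in granulosa-like cells. Of 14351 genes tested, 5108 were higher and 4629 lower in leukocyte-like cells at 5% FDR in edgeR. Fold changes are log2, leukocyte over granulosa, ± SE, and each gene chosen by list differed in the same direction in 4 of 4 libraries with an edgeR adjusted p between 5.98e-07 and 0.0101.

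Genes of steroid and cholesterol synthesis were lower in leukocyte-like cells. Of 13 measured steroid synthesis genes 11 were lower and 2 higher (median −4.80), led by HSD11B1 (−7.84 ± 0.62), which turns cortisone into cortisol, and the nuclear receptor NR5A2 (−7.02 ± 0.28). The list's camera adjusted p was 3.81e-07 with the preset correlation and adjusted p = 0.222 with an estimated correlation. Of 17 cholesterol genes 15 were lower (median −2.62), among them the sterol enzyme gene MSMO1 (−4.40 ± 0.27), with adjusted p = 1.01e-05 preset and adjusted p = 0.339 with an estimated correlation. Of 20 measured genes of the ovulatory LH response 14 were lower and 3 higher (median −3.63, adjusted p = 1.55e-05 preset and adjusted p = 0.244 with an estimated correlation). The protease PAPPA changed by −7.87 ± 0.45, and the ratio for LHCGR, the LH receptor, was 465 in favour of granulosa-like cells (95% counting interval 128 to 3844).

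Among fixed genes of ovulation, PGR, the progesterone receptor, fell by 6.65 ± 0.47, PTGES, a prostaglandin E synthase, by 7.05 ± 0.52, STAR by 6.96 ± 0.56, the EGF-like factor AREG by 3.48 ± 0.35, RUNX2 by 2.92 ± 0.18 and HIF1A by 1.85 ± 0.23. PTGS2, the inducible cyclooxygenase, was lower by a log2 fold change of −1.01 ± 0.35 in 3 of 4 libraries (edgeR adjusted p = 0.0334), and without replicate 1 the adjusted p was 0.0532, without replicate 2 0.0825 and without replicate 3 0.134 (0.000289 to 0.858 over all settings tried). Its direction turned at a mitochondrial limit of 10% (0.14, adjusted p = 0.858). EREG (0.96 ± 0.66, adjusted p = 0.232) and RUNX1 (0.22 ± 0.22, adjusted p = 0.407) did not pass the test. EREG passed without replicate 1 (1.55, adjusted p = 0.0302), and RUNX1 passed at a mitochondrial limit of 10% (0.60, adjusted p = 0.0453). Against the granulosa-like cells with at most 2% mitochondrial UMIs alone, a choice made after seeing the data, PTGS2 was 0.60 (adjusted p = 0.111), EREG 2.37 (adjusted p = 3.66e-10) and RUNX1 1.47 (adjusted p = 7.51e-05), and the LH response list had 6 of 13 measured genes lower and 4 higher (median 0.33). PTGER4, a prostaglandin E receptor, was higher in leukocyte-like cells (7.05 ± 0.36), as was PTGER2 (2.98 ± 0.24), while the prostaglandin transporter SLCO2A1 was lower (−7.75 ± 0.33). Over the 18 prostaglandin and leukotriene genes measured, 12 were higher and 4 lower (median 3.63, adjusted p = 0.00769 preset and adjusted p = 0.358 with an estimated correlation).

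Chemokine and cytokine genes were higher in leukocyte-like cells. Of 15 chemokines 12 were higher and 1 lower, with a median of 6.97, or 5.24 with genes of 0 counts at their bound (adjusted p = 1.13e-06 preset and adjusted p = 0.222 with an estimated correlation). CCL2, which attracts monocytes, stood at 175 ± 121 CPM against 0.359 ± 0.348 CPM (9.06 ± 0.32), and XCL1 was at least 90.9-fold higher. Of 23 cytokines 21 were higher and 2 lower (median 6.68, adjusted p = 1.38e-11 preset and adjusted p = 0.222 with an estimated correlation). TNF had a ratio of 589 (95% counting interval 105 to 23310) and TNFSF8 of 486 (86.9 to 19240). IL1B (7.95 ± 0.21), CXCL8 (4.75 ± 0.28) and TGFB1 (1.399 ± 0.15) were higher as well. Of 36 cytokine and chemokine receptors 26 were higher and 7 lower (median 3.07, adjusted p = 1.07e-06 preset and adjusted p = 0.244 with an estimated correlation), with CCR1 at 8.67 ± 0.30, CXCR6 at least 53.7-fold higher, TGFBR2 at 4.97 ± 0.20 and CXCR4 at 3.41 ± 0.17. Receptors higher in granulosa-like cells included IL6ST, the shared chain of the interleukin-6 receptor family (−4.45 ± 0.19), and IL1R1 (−2.35 ± 0.31). TNFRSF1A did not pass the test (−0.22 ± 0.13, adjusted p = 0.176).

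Most growth factor and matrix genes were higher in granulosa-like cells. Of 24 growth factors 16 were lower and 6 higher in leukocyte-like cells (median −2.27, adjusted p = 0.000181 preset and adjusted p = 0.224 with an estimated correlation). FGF2 was at least 58.0-fold lower and CCN2 had a ratio of 1034 in favour of granulosa-like cells (95% counting interval 185 to 40880), while VEGFA did not pass the test (0.53 ± 0.32, adjusted p = 0.175) except without replicate 1 (0.83, adjusted p = 0.0111) and against granulosa-like cells with at most 2% mitochondrial UMIs (1.05, adjusted p = 0.00523). Against those cells 9 of 18 growth factors were lower and 6 higher (median −0.87), 6 of 16 growth factor receptors lower and 4 higher (median −0.64), and 9 of 12 matrix genes lower and 3 higher (median −4.19). Of 20 growth factor receptors 14 were lower and 4 higher (median −1.83, adjusted p = 0.00259 preset and adjusted p = 0.222 with an estimated correlation), with EGFR at −7.65 ± 0.33 and BMPR1B at −6.87 ± 0.41. Of 17 extracellular matrix genes 14 were lower and 2 higher (median −5.82, adjusted p = 8.36e-08 preset and adjusted p = 0.222 with an estimated correlation), with EFEMP1 at −7.79 ± 0.34 and COL4A2, a basement membrane collagen chain, at −7.65 ± 0.35. Proteases and their inhibitors went both ways, with 11 of 21 higher and 7 lower (median 0.59, adjusted p = 0.426). SERPINB2 had a ratio of 396 in favour of leukocyte-like cells (109 to 3279) and SERPINA5 was at least 42.4-fold lower.

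Immune effector lists were almost uniformly higher in leukocyte-like cells. All 12 MHC class II presentation genes were higher (median 6.83, adjusted p = 2.2e-07 preset and adjusted p = 0.259 with an estimated correlation), with IFI30 at 8.25 ± 0.39. All 11 cytotoxic granule genes were higher (median 7.66, adjusted p = 9.94e-09 preset and adjusted p = 0.222 with an estimated correlation), with NKG7 at 8.18 ± 0.64 and CST7 at 8.06 ± 0.31. All 12 genes of classically activated macrophages (median 6.50, adjusted p = 1.26e-07 preset and adjusted p = 0.222 with an estimated correlation) and 11 of 15 genes of alternatively activated or resident macrophages (3 lower, median 7.65, adjusted p = 1.68e-07 preset and adjusted p = 0.259 with an estimated correlation) were higher. CCL3 changed by 8.08 ± 0.28, MARCO by 9.18 ± 0.27, and FOLR2 had a ratio of 727 (249 to 3529). Of 20 interferon response genes 18 were higher and 1 lower (median 3.57, adjusted p = 1.26e-07 preset and adjusted p = 0.222 with an estimated correlation), with MX2 at 7.10 ± 0.40 and OAS2 at 5.58 ± 0.32.

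The remaining lists had members on both sides and did not pass the test. Complement had 8 of 15 genes higher and 5 lower (adjusted p = 0.343), with C3AR1 at 7.81 ± 0.49 and CFD at 7.69 ± 0.30. Hypoxia and glycolysis had 4 of 19 higher and 10 lower (adjusted p = 0.152), with ANGPTL4 at −5.64 ± 0.39 and EGLN3 at 3.97 ± 0.48. Dissociation stress had 8 of 19 higher and 4 lower (adjusted p = 0.867), with JUN at −2.35 ± 0.24 and a ratio of 426 (118 to 3521) for HSPA6. Cell cycle genes had 4 of 18 higher and 5 lower (adjusted p = 0.788), with TPX2 at −1.99 ± 0.32 and UBE2C at −2.37 ± 0.62, which without replicate 3 was −1.26 (adjusted p = 0.0673, the highest over all settings, with 3.38e-23 the lowest). Against granulosa-like cells with at most 2% mitochondrial UMIs the cell cycle list had 1 of 17 higher and 9 lower (median −1.34) and dissociation stress 11 of 19 higher and 2 lower (median 1.12). Counts adjusted over the list alone were the same as over all genes except for growth factors (6 higher, 17 lower), alternatively activated macrophages (12 higher, 3 lower) and dissociation stress (7 higher, 4 lower). Free RNA was low, with granulosa markers in T-like cells at 0.702% ± 0.609 of their granulosa-like level and T markers in granulosa-like cells at 0.204% ± 0.114 (SD, n = 4).

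**Figure D3:**
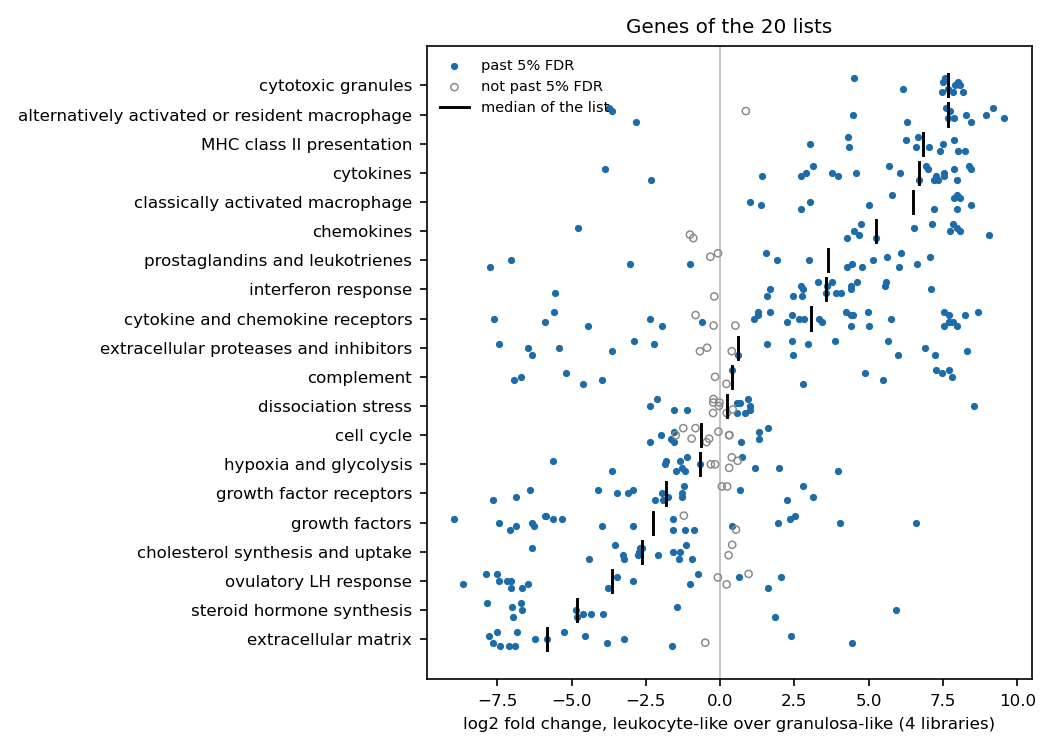
Log2 fold change (leukocyte-like over granulosa-like cells, horizontal axis) of every measured gene in the 20 lists, with filled points for genes past 5% FDR in edgeR and a bar at each list's median. Medians ran from −5.82 for extracellular matrix to 7.66 for cytotoxic granules.

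The second comparison set the phagocytes of the aspirates against the lymphocytes. Most measured resident macrophage, antigen presentation, protease, complement and growth factor genes were higher in monocyte or macrophage-like cells, and cytotoxic granule genes were higher in T and NK-like cells. As lists, 14 of 20 passed with the preset correlation and 0 with an estimated correlation (lowest adjusted p = 0.0857). GZMB, a granzyme, stood at 0.434 ± 0.147 CPM in monocyte or macrophage-like cells and 472 ± 149 CPM in T and NK-like cells (SD, n = 4). MARCO, a scavenger receptor, stood at 472 ± 273 and 0.557 ± 0.799 CPM. Of 11542 genes tested 4056 were higher and 3868 lower in monocyte or macrophage-like cells at 5% FDR in edgeR. Genes chosen by list differed in the same direction in 4 of 4 libraries with an edgeR adjusted p between 8.93e-12 and 0.000713.

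All 15 genes of alternatively activated or resident macrophages were higher (median 7.51, adjusted p = 1.04e-20 preset and adjusted p = 0.0857 with an estimated correlation), with F13A1 at least 362-fold higher and MARCO at 9.54 ± 0.24. All 11 MHC class II genes were higher (median 4.89, adjusted p = 2.63e-16 preset and adjusted p = 0.0857 with an estimated correlation), with IFI30 at 8.34 ± 0.15 and a ratio of 503 (172 to 2440) for CD86. All 11 cytotoxic granule genes were lower (median −8.04, adjusted p = 6.22e-28 preset and adjusted p = 0.108 with an estimated correlation), with GZMB at −10.12 ± 0.18 and PRF1 at −8.83 ± 0.23. Of 17 proteases and inhibitors 13 were higher and 2 lower (median 4.68, adjusted p = 6.87e-09 preset and adjusted p = 0.108 with an estimated correlation), with CTSL at 7.29 ± 0.21 and a ratio of 274 (75.6 to 2267) for SERPINB2. Of 13 complement genes 9 were higher and 1 lower (median 4.89, adjusted p = 2.02e-06 preset and adjusted p = 0.148 with an estimated correlation), with C2 at least 211-fold higher and C5AR1 at 9.52 ± 0.24. Of 11 genes of classically activated macrophages 8 were higher and 2 lower (median 2.48, adjusted p = 0.000211 preset and adjusted p = 0.121 with an estimated correlation), with FCGR1A at least 446-fold higher and IL1B at 8.96 ± 0.30.

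Growth factor and LH response genes were also mostly higher in the phagocytes. Of 12 growth factors 8 were higher and 1 lower, with a median of 5.06, or 4.53 with genes of 0 counts at their bound (adjusted p = 0.000277 preset and adjusted p = 0.108 with an estimated correlation). HBEGF, a ligand of the EGF receptor, changed by 8.19 ± 0.28, HGF had a ratio of 222 (39.6 to 8797) and VEGFA changed by 6.19 ± 0.23. Of 13 LH response genes 9 were higher and 3 lower (median 1.49, adjusted p = 0.00668 preset and adjusted p = 0.187 with an estimated correlation), with EREG at 7.16 ± 0.30 and TNFAIP6, which crosslinks cumulus matrix, at least 20.6-fold higher. PTGS2 changed by 5.24 ± 0.28, HIF1A by 3.03 ± 0.20, RUNX1 by 1.25 ± 0.12, IL1R1 by 2.87 ± 0.32 and TNFRSF1A by 1.65 ± 0.14. Of 11 chemokines 7 were higher and 4 lower, with a median of 7.35, or 5.75 at the bound (adjusted p = 0.0383 preset and adjusted p = 0.254 with an estimated correlation). CXCL8 changed by 7.35 ± 0.22, CCL2 by 8.74 ± 0.23, and CXCL2 had a ratio of 946 (262 to 7814). Of 13 growth factor receptors 9 were higher and 2 lower (median 1.30, adjusted p = 0.0125 preset and adjusted p = 0.338 with an estimated correlation), with NRP2 at 6.75 ± 0.24 and NRP1 at 6.51 ± 0.30. Of 6 extracellular matrix genes 3 were higher and 1 lower (median 3.32, adjusted p = 0.0104 preset and adjusted p = 0.254 with an estimated correlation), with THBS1 at 8.68 ± 0.18 and a ratio of 171 (30.4 to 6771) for NID1.

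Of 17 hypoxia and glycolysis genes 14 were higher and 1 lower (median 1.202, adjusted p = 0.000524 preset and adjusted p = 0.162 with an estimated correlation), with HK2 at 5.96 ± 0.33 and ADM at 5.62 ± 0.36. Of 20 interferon response genes 18 were higher and 2 lower (median 2.04, adjusted p = 0.000136 preset and adjusted p = 0.296 with an estimated correlation), and the lower genes were IFITM1 (−4.75 ± 0.23) and ISG20 (−3.96 ± 0.15). Of 19 dissociation stress genes 16 were higher and 1 lower (median 1.82, adjusted p = 3e-06 preset and adjusted p = 0.0857 with an estimated correlation), with EGR1 at 6.41 ± 0.25 and ATF3 at 5.48 ± 0.29. Prostaglandins and leukotrienes (11 of 17 higher, 3 lower, adjusted p = 0.0881), cytokines (11 of 22 higher, 7 lower, adjusted p = 0.141) and cytokine and chemokine receptors (22 of 34 higher, 9 lower, adjusted p = 0.106) did not pass the test. Within them PTGS1 was at least 68.9-fold higher, PTGDS changed by −6.94 ± 0.30, IFNG was at least 69.3-fold lower, CXCR3 was at least 203-fold lower and IL2RB changed by −8.82 ± 0.21. CXCR4 (−1.85 ± 0.14), PTGER2 (−1.94 ± 0.12) and RUNX2 (−1.34 ± 0.18) were lower in the phagocytes.

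Steroid synthesis (3 of 10 higher, 5 lower, adjusted p = 0.784), cell cycle (1 of 9 higher, 3 lower, adjusted p = 0.784) and cholesterol genes (8 of 17 higher, 6 lower, adjusted p = 0.7) did not pass either. The cholesterol list had a median of −0.26 but a mean of 0.32 and an upward test direction. AKR1C3 changed by −6.05 ± 0.32, TSPO by 2.08 ± 0.12, STARD4 by 2.10 ± 0.21, INSIG1 by 1.70 ± 0.15, TUBA1B by 1.75 ± 0.14 and STMN1 by −1.13 ± 0.22. TNF was higher in 3 of 4 libraries (1.09 ± 0.38, edgeR adjusted p = 0.0239), but it was 0.59 without replicate 4 (adjusted p = 0.0934) and 1.05 without replicate 1 (adjusted p = 0.0943; 1.62e-07 to 0.0943 over all settings). AREG (0.65 ± 0.22, adjusted p = 0.0216) passed in the full set and was 0.39 without replicate 1 (adjusted p = 0.114) and 0.49 without replicate 4 (adjusted p = 0.0872; 5.62e-07 to 0.263 over all settings). TGFBR2 (0.27 ± 0.11, adjusted p = 0.0476) had 0.120 without replicate 1, 0.226 without replicate 3 and 0.0669 without replicate 4 (0.00977 to 0.653 over all settings). PTGER4 was higher (0.54 ± 0.11) but not in cells thinned to 2000 UMIs (0.28, adjusted p = 0.165) or without the library block (0.54, adjusted p = 0.117), with 2.91e-06 to 0.165 over all settings. STAR (−0.70 ± 0.29, adjusted p = 0.0508), TGFB1 (−0.25 ± 0.11, adjusted p = 0.0578), IL6ST (−0.09 ± 0.14, adjusted p = 0.577) and PTGES (0.10 ± 0.37, adjusted p = 0.819) did not pass the test. STAR passed without replicate 3 (−1.13, adjusted p = 0.00478), without replicate 4 (−0.80, adjusted p = 0.0459) and without a filter on low counts (−0.58, adjusted p = 0.0129), with 0.00478 to 0.519 over all settings. Its levels here were low (10.1 ± 4.33 CPM in the phagocytes and 15.8 ± 11.2 in T and NK-like cells, against 1747 ± 859 in granulosa-like cells). Free RNA was not excluded as its source in either class. TGFB1 passed in thinned cells (−0.37, adjusted p = 0.0224) and without replicate 4 (−0.30, adjusted p = 0.0486), with 0.0224 to 0.44 over all settings. Adjusted over the list alone, the counts differed for steroid synthesis (3 higher, 6 lower), cholesterol (8 higher, 7 lower), cytokines (11 higher, 8 lower), classically activated macrophages (8 higher, 3 lower) and cell cycle (1 higher, 2 lower).

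The third comparison was between NK-like and T-like cells. Most measured cytotoxic granule genes and chemokines were higher in NK-like cells, and the lymphotoxin chain LTB and IL6R were higher in T-like cells. GZMB stood at 1850 ± 419 CPM in NK-like cells and 224 ± 194 CPM in T-like cells (SD, n = 4), and PRF1, which encodes perforin, at 1631 ± 127 and 259 ± 173 CPM. Of 7874 genes tested 866 were higher and 863 lower in NK-like cells at 5% FDR in edgeR, and DESeq2 called 562 and 546. Genes chosen by list and named here differed in the same direction in 4 of 4 libraries with an edgeR adjusted p between 5.74e-11 and 0.0103.

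Of 11 cytotoxic granule genes 9 were higher (median 1.64, adjusted p = 7.15e-10 preset and adjusted p = 0.284 with an estimated correlation), with GZMB at 3.08 ± 0.28 and PRF1 at 2.50 ± 0.23. Of 5 chemokines 4 were higher (median 2.71, adjusted p = 3.1e-07 preset and adjusted p = 0.284 with an estimated correlation), with CCL3 at 3.10 ± 0.27, XCL1 at 2.72 ± 0.32 and CCL4 at 2.27 ± 0.19. Cytokines had 2 of 12 higher and 4 lower (median −0.13, adjusted p = 0.0396 preset, downward, and adjusted p = 0.284 with an estimated correlation), with IL18 at 4.97 ± 0.47 and LTB at −4.01 ± 0.19. Among receptors, with 7 of 20 higher and 7 lower (adjusted p = 0.705), IL6R was at least 17.5-fold lower and CCR6 had a ratio of 32.2 in favour of T-like cells (5.71 to 1279). AKR1C3, a steroid and prostaglandin reductase, was higher by 3.74 ± 0.18, the prostaglandin D synthase PTGDS by 3.002 ± 0.30, TBXAS1 by 2.54 ± 0.32, ADAMTS1 by 2.50 ± 0.38, AREG by 2.28 ± 0.22, PDGFRB by 2.02 ± 0.47, IFITM3 by 3.06 ± 0.21, IFIT3 by 1.51 ± 0.35, MVD by 1.45 ± 0.18 and ZFP36 by 0.97 ± 0.17. SOCS3 changed by −3.18 ± 0.45, PDK1 by −1.24 ± 0.27, NDRG1 by −1.198 ± 0.22, CXCR4 by −1.201 ± 0.13 and IL6ST by −1.68 ± 0.24.

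No other list passed the test between NK-like and T-like cells. Higher and lower members were 1 and 1 of 6 for steroid synthesis, 6 and 0 of 13 for cholesterol, 4 and 1 of 8 for the LH response, 3 and 2 of 10 for prostaglandins, 0 and 0 of 3 for growth factors, 1 and 0 of 3 for growth factor receptors, 3 and 1 of 7 for proteases and 0 and 2 of 6 for MHC class II. They were 0 and 1 of 3 for complement, 3 and 2 of 5 for classically activated macrophages, 0 and 4 of 13 for hypoxia, 3 and 1 of 16 for interferon response, 2 and 6 of 15 for dissociation stress and 3 and 0 of 6 for cell cycle. Adjusted over the list alone the counts changed for cytokines (2 and 5), receptors (8 and 9), cytotoxic granules (9 and 1), MHC class II (1 and 2), interferon response (4 and 2) and cell cycle (5 and 0). Steroid synthesis had a median of −0.03 with a mean of 0.55, and the receptors a median of −0.05 with an upward test direction. Some calls were lost with 3 libraries. Without replicate 3 MCM5 (1.10 ± 0.29) was 0.55 (adjusted p = 0.159) and TUBA1B (0.79 ± 0.21) was 0.34 (adjusted p = 0.0758). The fold moved less for CTSB (−0.92 ± 0.24), at −0.78 without replicate 2 (adjusted p = 0.0687), and for TGFB1 (0.50 ± 0.11) and RUNX2 (−1.29 ± 0.38, lower in 3 of 4 libraries), at 0.45 (adjusted p = 0.0667) and −1.05 (adjusted p = 0.196) without replicate 1. TNFRSF1A (0.66 ± 0.20) was 0.44 (adjusted p = 0.318) without replicate 1 and 0.54 (adjusted p = 0.141) without replicate 2. MCM5 and TUBA1B had an adjusted p of 0.195 and 0.685 when doublets were not removed. Over all settings the adjusted p ran from 8.47e-05 to 0.195 for MCM5, 4.72e-06 to 0.685 for TUBA1B, 0.00147 to 0.0863 for CTSB, 0.000242 to 0.159 for TGFB1, 0.00151 to 0.196 for RUNX2 and 0.00405 to 0.318 for TNFRSF1A. Without the library block ZFP36 (0.96, adjusted p = 0.545) and PDGFRB (1.88, adjusted p = 0.0595) were lost too, with 1.71e-06 and 2.46e-05 as their lowest adjusted p over all settings. TGFBR2 (−0.37, adjusted p = 0.132), STAR (0.36, adjusted p = 0.418), RUNX1 (−0.13, adjusted p = 0.693), HIF1A (−0.11, adjusted p = 0.745), IFNG (0.21, adjusted p = 0.790), PTGER4 (0.09, adjusted p = 0.791) and PTGER2 (0.07, adjusted p = 0.814) did not pass the test.

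Each leukocyte class was then compared with the other leukocyte-like cells of the same library. T-like cells had 3541 genes higher and 4021 lower of 12176, and 10 of 11 cytotoxic granule genes were higher (median 1.86, adjusted p = 0.00419 preset and adjusted p = 0.463 with an estimated correlation). In the third comparison 9 of these 11 genes were higher in NK-like than in T-like cells. Against the other leukocyte-like cells, IL32 (5.44 ± 0.47), CXCR6 (4.35 ± 0.36) and FLT3LG (4.13 ± 0.19) were higher in T-like cells, and FCGR1A, CXCL2 and F13A1 were at least 289-fold, 408-fold and 261-fold lower. NK-like cells had 1563 genes higher and 2692 lower of 11493, with all 11 cytotoxic granule genes higher (median 3.63, adjusted p = 9.32e-16 preset and adjusted p = 0.14 with an estimated correlation). AKR1C3 (5.22 ± 0.25), IL2RB (5.09 ± 0.27) and XCL1 (4.89 ± 0.41) were higher in NK-like cells, and IL1B, CCL2 and CFP were at least 140-fold, 114-fold and 93.2-fold lower. Monocyte or macrophage-like cells had 3606 genes higher and 3554 lower of 11762, with all 15 genes of alternatively activated or resident macrophages higher (median 4.15, adjusted p = 1.34e-14 preset and adjusted p = 0.0892 with an estimated correlation) and 9 of 12 complement genes higher (adjusted p = 1.61e-06 preset and adjusted p = 0.163 with an estimated correlation). C2 (6.81 ± 0.40), SERPINB2 (6.38 ± 0.36) and LYVE1 (6.004 ± 0.32) were higher, GZMB was lower (−9.52 ± 0.16), and CXCR3 and CXCR6 were at least 156-fold and 51.8-fold lower.

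Dendritic-like cells had 1873 genes higher and 2001 lower of 11428. Of 12 MHC class II genes 11 were higher and 1 lower (median 2.34, adjusted p = 7.16e-14 preset and adjusted p = 0.404 with an estimated correlation), 7 of 16 cell cycle genes were higher (adjusted p = 0.000222 preset and adjusted p = 0.566 with an estimated correlation) and 8 of 17 cholesterol genes were higher and 1 lower (adjusted p = 0.00798 preset and adjusted p = 0.542 with an estimated correlation). CCL22, which attracts T cells, had a ratio of 535 (182 to 2610), IL1R2 changed by 5.13 ± 0.35 and AREG by 4.29 ± 0.47, with AREG at 797 ± 431 CPM against 45.4 ± 20.3 CPM. SERPINB2 and FASLG were at least 60.3-fold and 13.3-fold lower and IL2RB had a ratio of 253 in favour of the other cells (45.4 to 10010). Without replicate 2 or 3 the counts moved by over 1.5 times, to as few as 1177 higher and 1331 lower.

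B-like cells, tested in 3 libraries, had 753 genes higher and 1625 lower of 11199. IL7 (3.84 ± 0.85), CD40 (3.56 ± 0.31) and LAMC1 (3.23 ± 1.09) were higher, and THBS1, C5AR1 and TGFBI were at least 109-fold, 71.0-fold and 60.7-fold lower. Without 1 library the B-like counts fell to as few as 339 and 966. Neutrophil-like cells, also tested in 3 libraries and with a median of 657 UMIs, had 463 genes higher and 1155 lower of 10671, and 363 and 2441 with DESeq2's size factors. The median log2 fold change of all genes was −2.43 there and those size factors shifted it by a further −0.50, so lower values in neutrophil-like cells are not separable from their low depth. MMP25 (6.96 ± 0.52), MMP9 (4.40 ± 0.51) and COL18A1 (4.10 ± 0.74) were higher, and NKG7, HLA-DMA and TGFBI were at least 17.3-fold, 9.36-fold and 7.30-fold lower. Without each of the 3 libraries in turn the neutrophil-like counts lay between 46 and 220 higher and between 353 and 528 lower.

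Lists in these class comparisons passed mostly in the downward direction for lymphocytes. With the preset correlation 1 list was higher and 16 lower in T-like cells, 1 and 14 in NK-like cells, 8 and 1 in monocyte or macrophage-like cells, 3 and 6 in dendritic-like cells, 0 and 14 in B-like cells and 1 and 3 in neutrophil-like cells. With an estimated correlation none passed in any of the 6 classes, and the lowest adjusted p was 0.0946, 0.0549, 0.0892, 0.197, 0.162 and 0.826 in the same order. In NK-like cells the extracellular matrix list had a median of 0.14 but a mean of −2.75 and a downward test (adjusted p = 0.00838 preset and adjusted p = 0.15 with an estimated correlation). In neutrophil-like cells the receptor list had a median of 0.13, a mean of −1.23 and an upward test, which compares it with the other genes (adjusted p = 0.000292 preset and adjusted p = 0.826 with an estimated correlation).

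Ligands were then traced to the class with the highest level in CPM. CPM are shares of a class's UMIs and take no account of UMIs per cell, which differed between classes. Which class had most UMIs of a ligand per cell was not determined. Granulosa-like levels are mainly those of sub-cluster 1, which gave most UMIs of that class. Of 79 chemokines, cytokines and growth factors with at least 10 counts, 42 were highest in 1 class in every library that had it. Granulosa-like cells held 15 of them, monocyte or macrophage-like cells 12, NK-like and neutrophil-like cells 4 each, T-like and dendritic-like cells 3 each and B-like cells 1. In granulosa-like cells MIF reached 2589 ± 165 CPM, the midkine gene MDK 132 ± 37.2, INHBA, which encodes the activin A subunit, 112 ± 82.4, INHBB 83.9 ± 50.1, CCN1 55.5 ± 10.9 and GDF15 40.2 ± 20.5 CPM (SD, n = 4), and the others were CXCL6, VEGFC, PGF, PDGFA, FGF2, HGF, IGF2, PROS1 and CCN2. HGF was close between granulosa-like cells (22.8 ± 6.52 CPM) and monocyte or macrophage-like cells (17.9 CPM), and by the share of cells with a UMI at 2000 UMIs per cell it was highest in the latter.

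Monocyte or macrophage-like cells held GRN (729 ± 139 CPM), SPP1 (533 ± 633), CCL2 (296 ± 150), HBEGF (235 ± 75.1), CXCL2 (146 ± 157), TNFSF13 (103 ± 11.6), CXCL3 (101 ± 79.4) and IL10 (88.0 ± 52.7), with CXCL10, CCL7, CCL8 and NRG1 below 20 CPM. NK-like cells held CCL4 (1214 ± 277 CPM), TGFB1 (426 ± 91.9), XCL2 (255 ± 79.7) and XCL1 (101 ± 84.5). T-like cells held IL32 (1497 ± 309 CPM), FLT3LG (101 ± 41.9) and TNFSF8 (20.4 ± 8.28), and dendritic-like cells held CCL22 (45.4 ± 24.1), TNF (36.2 ± 28.5) and CCL17 (31.5 ± 60.5). Neutrophil-like cells held TNFSF10 (717 ± 276 CPM, n = 3), OSM (189 ± 144), TNFSF14 (154 ± 32.2) and IL1RN (128 ± 16.5), and B-like cells held IL7 (20.2 ± 15.9, n = 3). Few UMIs lie behind some of these, with 17, 36 and 4 for TNFSF10 in replicates 1, 2 and 4. In the same replicates there were 2, 5 and 3 for OSM, 3, 9 and 1 for TNFSF14, 2, 8 and 1 for IL1RN and 7, 1 and 3 for IL7. CCL17 had 231 in replicate 1 and 2, 4 and 1 in replicates 2 to 4, so replicate 1 carried its mean level. The highest class in single libraries thus rests on few UMIs for these 6. SPP1 had 198, 2404, 942 and 6357 UMIs in monocyte or macrophage-like cells of replicates 1 to 4. CXCL2 had 149, 248, 847 and 1669 there, so replicate 4 weighs most in both means. With each cell thinned to 2000 UMIs 37 of the 42 had the same class highest by share of cells, and the 4 neutrophil ligands had no value because no neutrophil-like cell reached that depth.

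Granulosa-like cells expressed receptors for several of these ligands. These receptor levels too are mainly those of sub-cluster 1. IL6ST and OSMR, which together bind oncostatin M, stood at 1061 ± 100 and 49.8 ± 8.61 CPM. The TNF receptor TNFRSF1A stood at 106 ± 16.6 CPM, the interleukin-1 receptor IL1R1 at 106 ± 54.9, TNFRSF12A at 265 ± 40.8, the interferon-gamma receptor chain IFNGR2 at 58.2 ± 6.49, the interleukin-10 receptor chain IL10RB at 38.01 ± 8.92, and EGFR, which binds AREG, EREG and HBEGF, at 38.3 ± 4.31 CPM. IL10RA (1.001 ± 0.820 CPM), TGFBR2 (2.56 ± 1.16), TNFRSF1B (1.93 ± 0.988), CCR1 (0.398 ± 0.185) and MET (0.756 ± 0.320) were low. In cells thinned to 2000 UMIs, 64.7% of granulosa-like cells had a UMI of IL6ST and 0.153% a UMI of TGFBR2.

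**Figure D4:**
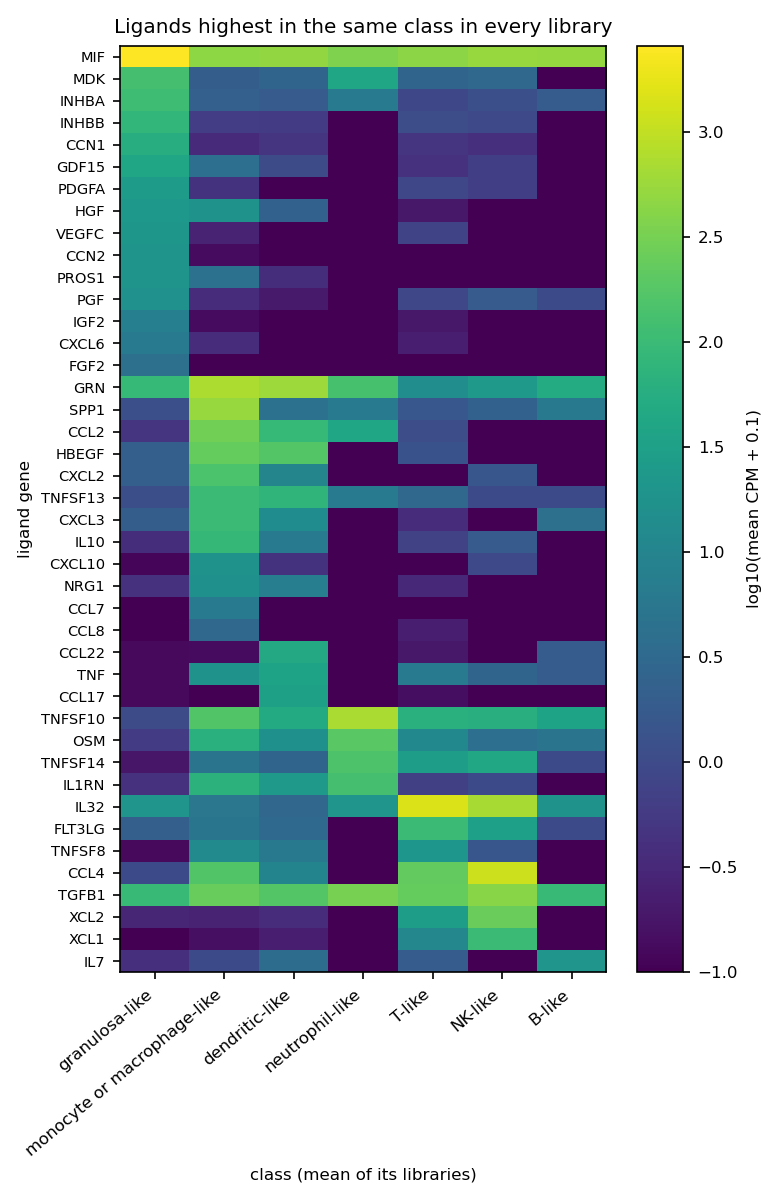
Mean level of the 42 assigned ligands (log10 of CPM plus 0.1, colour) in 7 cell classes (columns), with ligands grouped by the class that held the highest level in every library with that class. MIF in granulosa-like cells reached 2589 CPM, IL32 in T-like cells 1497 CPM and CCL4 in NK-like cells 1214 CPM.

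Re-clustering divided the granulosa-like cells into 4 sub-clusters. They are called granulosa-like from the first clustering. The marker rule, applied to each against the other granulosa-like cells, left sub-clusters 1 and 3 unnamed. The closest class of sub-cluster 1 was theca or stroma, with 2 markers. Sub-cluster 1 (568 cells, median 44473 UMIs, 13.3% mitochondrial) had most LH response genes higher than in the other granulosa-like cells (list adjusted p = 0.324 with an estimated correlation), with EREG at 111 ± 51.1 against 3.12 ± 3.62 CPM (log2 fold change 4.70 ± 0.26, SD and SE, n = 4), ADAMTS1 at 342 ± 57.0 against 17.7 ± 4.10 CPM (4.52 ± 0.20) and ADAMTS9 at 238 ± 42.9 against 19.9 ± 7.64 CPM (4.002 ± 0.24). In sub-cluster 2 (387 cells, 2401 UMIs, 0.624% mitochondrial) 9 of 17 cell cycle genes were higher, a list with an adjusted p of 0.25 with an estimated correlation. Sub-cluster 3 (385 cells, 3289 UMIs, 1.18% mitochondrial) had higher levels of steroid synthesis genes CYB5A and HSD17B1. Sub-cluster 4 (211 cells, 27080 UMIs, 12.7% mitochondrial) had sums in only 2 libraries and was not tested on its own. Its STAR level was 45.2 CPM of non-mitochondrial UMIs against 1920 in sub-cluster 1. CYP19A1, which encodes aromatase, was at 1236 against 231 CPM. Sums weigh cells by their UMIs, so sub-cluster 4 was a large part of the cells that sub-cluster 1 was compared with. It gave 188441 of 232855, 2900160 of 4395593, 2970939 of 4070279 and 81300 of 175532 of their UMIs in replicates 1 to 4.

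In sub-cluster 1 2053 genes were higher and 1834 lower of 11695. Of 20 LH response genes 17 were higher and 1 lower, or 18 and 1 adjusted over the list alone (median 2.52, adjusted p = 5.2e-10 preset and adjusted p = 0.324 with an estimated correlation). Hypoxia and glycolysis had 13 of 18 higher and 1 lower, or 15 and 2 adjusted over the list alone (adjusted p = 1.26e-05 preset and adjusted p = 0.324 with an estimated correlation), and prostaglandins 7 of 10 higher (adjusted p = 0.00126 preset and adjusted p = 0.324 with an estimated correlation). All 13 cell cycle genes were lower (median −3.53, adjusted p = 5.2e-10 preset and adjusted p = 0.324 with an estimated correlation), with MKI67 at −8.38 ± 0.43, UBE2C at −7.31 ± 0.44 and a ratio of 119 (31.8 to 1003) for PDGFB, a growth factor. Interferon response genes were lower in 12 of 15 (median −1.34, adjusted p = 0.000445 preset and adjusted p = 0.364 with an estimated correlation). Without replicate 2 or 3 the counts moved by over 1.5 times, to as few as 824 higher and 785 lower.

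In sub-cluster 2, tested in 3 libraries, 821 genes were higher and 1308 lower of 8420. Of 17 cell cycle genes 9 were higher and 1 lower (median 0.97), with TYMS at 1.98 ± 0.32, UBE2C at 1.95 ± 0.31 and STMN1 at 1.86 ± 0.23. LH response genes were lower in 12 of 17, cholesterol genes in 11 of 17 and extracellular matrix genes in 11 of 12. Each of these 4 lists passed with the preset correlation and had an adjusted p of 0.25 with an estimated correlation. Single genes included FOSB at −4.03 ± 0.31, NFKBIZ at −4.03 ± 0.54 and PAPPA at −3.79 ± 0.37. In sub-cluster 3 537 genes were higher and 1618 lower of 8401. DESeq2's size factors gave 624 higher and 2500 lower there and shifted the median of all genes by −0.20. CYB5A (1.32 ± 0.26), HSD17B1 (1.19 ± 0.26) and DHCR7 (0.97 ± 0.25) were higher, while 3 of 12 steroid synthesis genes were higher and 2 lower. LH response genes were lower in 11 of 18 with 2 higher, growth factor receptors in 8 of 10 and extracellular matrix genes in 10 of 13 with 1 higher. These 3 lists passed with the preset correlation and had an adjusted p of 0.439 with an estimated correlation. The lists named are a part of those that passed with the preset correlation. In all 8 lists were higher and 3 lower in sub-cluster 1, 2 and 10 in sub-cluster 2 and 0 and 6 in sub-cluster 3. Single genes included FOSB at −4.81 ± 0.38, PAPPA at −4.12 ± 0.40 and a ratio of 42.0 in favour of the other cells (11.6 to 347) for NFKBIZ. The counts moved by over 1.5 times without replicate 2 or 3 in sub-cluster 2, to as few as 32 higher and 243 lower, and without replicate 1, 2 or 3 in sub-cluster 3, to as few as 78 and 610. Because sub-clusters 2 and 3 had far fewer UMIs per cell than sub-cluster 1 and few nuclear transcripts, differences between them include differences in RNA content. By UMIs, the other granulosa-like cells in these tests were mostly sub-cluster 1. For sub-cluster 2 it gave 7927946 of 11835932, 12806994 of 16231632 and 1500742 of 1620792 in replicates 2 to 4. For sub-cluster 3 it gave 7553120 of 7748559, 7927946 of 11315713, 12806994 of 16423574 and 1500742 of 1637524 in replicates 1 to 4. The results of sub-clusters 2 and 3 are therefore not independent of those of sub-cluster 1.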

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

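The tests of free RNA, of lower depth and of the platelet-like cluster were chosen only after the result was seen, and so were the counts over other splits.

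The granulosa-like barcodes with few mitochondrial and MALAT1 UMIs (clusters 1, 6 and 11) may be cells or cell fragments without a nucleus, since 8 of 9 measured nuclear non-coding RNAs were lower in them than in clusters 4 and 12, with a median log2 ratio of −2.71 (−3.56 to −2.52 over the libraries), against 0.53 for ribosomal protein genes. For free RNA in droplets, the ratio of leukocyte to granulosa marker UMIs was compared with that in haemoglobin-rich barcodes. In these clusters it was 0.955% (0.633 to 1.47) of the latter, over the 4 libraries as a pool. These clusters were matched to the granulosa class by the same granulosa markers, which lowers the ratio in advance. The reference held 33 leukocyte and 86 granulosa UMIs, 78 of the latter in replicate 2. The ratio therefore does not decide on free RNA. A first form, which asked for at least 10 granulosa UMIs in the haemoglobin-rich barcodes of each library, left too few libraries to decide, and the pool was chosen after the single values had been seen, which were 2.42%, 0.403% and 0.119% in replicates 2 to 4, with 8 leukocyte and 0 granulosa UMIs in replicate 1. Clusters 4 and 12 thinned to 2000 UMIs kept a median of 6.26% MALAT1 (5.97 to 9.11). Random thinning keeps a gene's share of UMIs on average, so this run could not decide on lower depth. Loss of the nucleus alone does not account for the median mitochondrial share of 0.552 to 0.92% against 13.5 and 12.9% in clusters 4 and 12, which no test addressed, so what these barcodes are stays open, and no biological explanation was tested.

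The platelet-like cluster of 48 cells carried leukocyte transcripts. Platelets alone would lack them, but its leukocyte marker level was 109% of that of all leukocyte-like cells. Its monocyte or macrophage marker level was 160% of the monocyte or macrophage-like level while its T marker level was 0.58% of the T-like level, so platelets captured together with monocytes are a candidate explanation. Whether they were bound in the follicle or joined after sampling was not tested.

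The higher LH response in granulosa-like sub-cluster 1 might come from loss of nuclear RNA in the other granulosa-like barcodes. Against this stands a comparison with sub-cluster 4, which has a similar nuclear RNA content. The list's median log2 ratio of sub-cluster 1 over sub-cluster 4 was 3.67 (3.37 and 3.96 in the 2 replicates with all 4 sub-clusters). Sub-cluster 4 was also a large part of the other granulosa-like cells in the test of sub-cluster 1, so these ratios are not independent of it. AREG (7.25 and 6.88) and ADAMTS1 (6.66 and 8.33) were higher in sub-cluster 1, and PGR (−1.62 and −1.97) and NRIP1 (−1.05 and −1.40) were lower. A difference in response to the ovulatory signal between granulosa-like cells stays a hypothesis, and a difference in position in the follicle was not tested.

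Some genes had 1 library far from the other 3. In replicate 4 leukocyte-like cells had TNF at 33.6 CPM (others 10.7 to 12.1), CCL3 at 419 CPM (71.0 to 112) and CXCR4 at 118 CPM (144 to 149). Monocyte or macrophage-like cells of replicate 4 had IL1B at 811 CPM (122 to 195), ATF3 at 62.4 CPM (24.7 to 30.2) and IL1R1 at 32.2 CPM (12.8 to 14.2). T-like cells of replicate 4 had NDRG1 at 20.4 CPM (37.6 to 38.9), and its granulosa-like cells had PGR at 9.55 CPM (21.0 to 22.2). Replicate 1 had TNFAIP6 at 8.64 CPM in monocyte or macrophage-like cells (3.16 to 3.69), and replicate 3 had HGF at 11.6 CPM there (19.6 to 20.4). NK-like cells of replicate 3 had MCM5 at 120 CPM (32.2 to 45.0) and TUBA1B at 1013 CPM (208 to 284). In replicate 2 STAR stood at 32.6 CPM in T and NK-like cells (8.95 to 11.4) and IL6ST at 87.6 CPM in T-like cells (43.8 to 47.6). Replicate 2 also had the most granulosa marker RNA in T-like cells (62.2 CPM, 1.53% of the granulosa-like level, against 0.191 to 0.790% in the others), so free RNA was not excluded as a source of its STAR there. These are 14 of 183 measures, where chance gives about 1 in 20, or 9.2, and 8 of the 14 fell in replicate 4.

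Barcodes outside the comparisons also carried signal. The 1735 barcodes over the mitochondrial limit had STAR at 1069 CPM and PTPRC at 236 CPM of non-mitochondrial UMIs. The unnamed cluster 1 had STAR at 3495 CPM and PTPRC at 9.63 CPM. The 401 barcodes under the gene minimum had a median of 94.7% haemoglobin UMIs.

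With 4 libraries only 8 splits exchange the cell classes within libraries, and with 3 libraries only 4, too few for a share under 0.05. The other splits mix the classes, which leaves the difference between classes in the residual, so few genes were bound to pass in them. The classes were also made from the same counts, so these numbers do not decide on chance. In each comparison 1 split, the real one, gave as many genes. Leukocyte-like against granulosa-like cells gave 9737 genes and the highest other split 0, monocyte or macrophage-like against T and NK-like cells 7924 and 0, and NK-like against T-like cells 1729 and 0. The class comparisons gave 7562 genes for T-like, 4255 for NK-like, 7160 for monocyte or macrophage-like, 3874 for dendritic-like, 2378 for B-like and 1618 for neutrophil-like cells, each with 0 in the highest other split. Granulosa-like sub-clusters 1, 2 and 3 gave 3887, 2129 and 2155 genes, with 0, 0 and 30 in the highest other split.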

How the results depend on the processing

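Cluster 1 counted as granulosa, the granulosa-like cells divided by mitochondrial share and the settings for the difference of shares, apart from leaving out each library, were tests chosen only after the result was seen, and the other settings were planned.

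The leukocyte-like share stayed between 54.0% and 67.3% when each library was left out and between 54.9% and 63.2% in the other settings. Its difference from the granulosa-like share stayed between 29.96 and 52.2 points when each library was left out and between 25.4 and 45.9 in the other 9 settings, in 3 of which replicate 2 had the larger granulosa-like share (no cell filter, −0.723 points; clustering resolution 0.5, −3.96 points; cluster 1 counted as granulosa), and the cause was not tested.

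For leukocyte-like against granulosa-like cells, 15 of 16 settings kept the number of higher genes within 1.5 times (3964 to 5688) and 14 of 16 the number of lower genes (3465 to 5803), and leaving out each library gave 4577 to 5006 and 3775 to 4982. For monocyte or macrophage-like against T and NK-like cells 12 of 13 settings did so (3600 to 5059 higher, 3276 to 4304 lower), and leaving out each library gave 3715 to 3949 and 3520 to 3693. For NK-like against T-like cells 10 of 13 did so in each direction (721 to 945 higher, 579 to 965 lower), with 579 to 897 and 612 to 906 without each library. The counts for T-like, NK-like and monocyte or macrophage-like cells against the other leukocyte-like cells stayed within 1.5 times in all 4 settings run and without each library.

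Fewer genes passed the threshold with each cell thinned to 2000 UMIs, a setting that also left out the cells with fewer UMIs (246 of 1551 granulosa-like and 298 of 4245 leukocyte-like cells), so the part of depth alone was not tested. Leukocyte-like against granulosa-like cells then gave 2948 higher and 2607 lower, monocyte or macrophage-like against T and NK-like cells 2299 and 2196, and NK-like against T-like cells 445 and 445. Against granulosa-like cells with at most 2% mitochondrial UMIs 2381 genes were lower in leukocyte-like cells, and the cause was not tested.

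With an estimated correlation 0 lists passed in each comparison. Camera then allows for the correlation between a list's genes and also rests on the residual degrees of freedom, 3 or 2 here. On so few a list rarely passes, and the part of each was not tested. By fry, which asks a different question, 17 of 20 lists passed in the first comparison and 17 of 20 in the second. In the third 9 of 18 passed by fry, and in neutrophil-like cells 0 of 20. Without a filter on low counts 1319 genes were lower in NK-like than in T-like cells, 218 were higher in neutrophil-like cells, 279 were higher in sub-cluster 2 and 2593 were lower in sub-cluster 3. DESeq2 gave 562 higher and 546 lower genes in NK-like against T-like cells, 454 and 912 in B-like cells, 234 higher in neutrophil-like cells, 220 and 557 in sub-cluster 2 and 245 higher in sub-cluster 3. DESeq2's size factors in edgeR gave 2441 lower genes in neutrophil-like cells and 2500 in sub-cluster 3. For these settings the cause was not tested.

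Without the library block 570 genes were higher in NK-like than in T-like cells, 1192 in dendritic-like cells, 1340 in sub-cluster 1, 184 in sub-cluster 2 with 650 lower, and 232 in sub-cluster 3, and PTGES in monocyte or macrophage-like cells against T and NK-like cells was −0.00359. Leaving it out moved no other count of genes by over 1.5 times, and 13 single genes no longer passed.

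Leaving out each library gave 1177 to 1879 higher and 1331 to 1947 lower genes in dendritic-like cells (moved without replicates 2 and 3), 339 to 649 and 966 to 1465 in B-like cells (without 1 and 2), and 46 to 220 and 353 to 528 in neutrophil-like cells (without any). Sub-cluster 1 gave 824 to 2208 and 785 to 2175 (without 2 and 3), sub-cluster 2 gave 32 to 1207 and 243 to 1721 (without 2 and 3), and sub-cluster 3 gave 78 to 902 and 610 to 1748 (without 1, 2 and 3). These runs use fewer libraries.

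Of the values for single genes 2611 kept their direction and side of the threshold, 60 (15 genes) no longer passed, 11 (5 genes) newly passed and 18 (8 genes) changed sign. Each gene that changed sign was short of the threshold in the full set except PTGS2. In leukocyte-like against granulosa-like cells PTGS2 was 0.14 with at most 10% mitochondrial UMIs and 0.60 against granulosa-like cells with at most 2%, VEGFA was −0.0136 in thinned cells and RUNX1 ranged from −0.00573 (without replicate 2) to 0.402 when each library was left out. In monocyte or macrophage-like against T and NK-like cells IL6ST was 0.0289 without a filter on low counts, 0.0217 in thinned cells and −0.209 to 0.0739 (without replicate 2) when each library was left out, and PTGES was −0.0596 (without replicate 1) to 0.0108 (without replicate 4), the 2 runs in which it passed the count filter. In NK-like against T-like cells PTGER2 was −0.0219 without a filter, −0.000609 with the tested lists kept among the clustering genes, −0.0937 in thinned cells and −0.0243 (without replicate 3) to 0.118 when each library was left out. PTGER4 there was −0.0522 with at most 10% mitochondrial UMIs, −0.117 with each library clustered on its own and −0.0965 (without replicate 1; −0.0306 without replicate 3) to 0.223, and HIF1A was −0.219 to 0.104 (without replicate 1). For these genes the cause was not tested.

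Thinning to 2000 UMIs left no neutrophil-like cell and so no value for their ligands.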

Other observations

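The comparison of the low and high UMI sub-clusters was planned before the result was seen, and the counts of sub-clusters were tests chosen only after the result was seen.

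Granulosa-like barcodes of low and of high UMI count divided partly along the same genes. If both hold the same pair of granulosa-like states, sub-cluster 2 should differ from sub-cluster 3 as sub-cluster 4 differs from sub-cluster 1. Across list genes, without STAR because its levels had been seen, the Pearson r between those log2 ratios was 0.46 in replicate 3 (185 genes, 61.1% of the same sign) and 0.78 in replicate 2 (203 genes, 74.9%). The same pair of states may therefore occur among barcodes with and without nuclear RNA, which is a hypothesis from 2 replicates.

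When the leukocyte-like cells were clustered again, 2 monocyte or macrophage-like sub-clusters divided by library. Sub-cluster 7 held 1, 2, 155 and 104 cells in replicates 1 to 4 and sub-cluster 11 held 99, 82, 8 and 1. The naming rule called 115 cells mast or basophil-like and 19 cells plasma-like in that second clustering, with 11, 19, 75 and 10 of the former in replicates 1 to 4, whereas the first clustering, from which the shares of these classes come, held 19 mast or basophil-like cells and no plasma-like cell. The first clustering called those 19 plasma-like cells plasmacytoid dendritic-like.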
